A study of Rattus norvegicus with 4 samples.

How the data were processed

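Rat bone marrow-derived mesenchymal stem cells were cultured in osteogenic medium on flat titanium discs or on titanium discs carrying a wave-forming nanotexture written with a femtosecond laser. Days are used as the labels' titles give them, since the protocol text leaves open how they relate to seeding. Total RNA was taken at day 1 and at day 3, and 1 sequencing library was analysed for each of the 4 combinations of surface and day. Libraries were made with the NEBNext Ultra II Directional kit, per the labels' protocols. Reads were aligned with TopHat to the rat genome build mRatBN7.2, per the submitters' processing notes. The version of TopHat, the counting tool, its strand setting, the gene annotation and any filter on reads are not given in the sources used here.

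The deposited values are raw read counts per gene symbol, in 1 table per library. That unit was read from the values, which were whole numbers with a different total in each library. Each table held 41702 entries under 41039 distinct symbols, and each repeated symbol was a transfer RNA name whose counts were added together. Symbols were compared with a RefSeq gene table of another assembly, GRCr8, used for names alone. Of the distinct symbols, 29014 matched a symbol in that table and 2027 more matched a synonym. Genes are named here by the symbol in the deposited tables, which give no coordinates. Hdac6, Dcstamp, Saa3, Car9 and Hspa1a were on the gene lists described below and were not analysed here.

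Library totals were 13874517 reads for flat day 1, 10575759 for wave day 1, 20320492 for flat day 3 and 19943517 for wave day 3. A count of 0, taken as fewer than 3 reads, therefore allows a level of up to 0.216, 0.284, 0.148 and 0.150 CPM, the reads of a gene scaled by the library total, in those libraries. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which were 0.972, 0.969, 1.03 and 1.03 in the same order. The 13086 genes at 1 CPM or more in at least 1 library were analysed. A log2 ratio was taken between libraries on CPM plus 0.5, which understates differences of low genes.

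A gene was counted as at least 2-fold higher or lower when its ratio reached 2-fold and the exact 95% conditional binomial interval of the read counts excluded equality. That interval is computed on the counts without the added 0.5 CPM, so for genes with few reads it can lie off the printed ratio. With 1 library per group no such comparison has a replicate check, and no p-value is given for it. Intervals and floors cover counting error only and leave out variation between cultures. They can understate even counting error, because PCR reads without molecular identifiers are not independent molecules. A ratio against a library with 0 reads is given as a lower bound, computed with 3 reads in that library and the reads of the other library taken as exact, so the counting interval can begin below it.

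The only test among libraries was edgeR's quasi-likelihood test of an additive model with day and surface as terms, adjusted by the Benjamini-Hochberg method at 0.05. This model leaves 1 residual degree of freedom and assumes that the surface effect is the same on both days. Its spread is the departure from that assumption, shared across genes with 32.2 prior degrees of freedom, and nothing says whether further cultures would vary more. A test of the difference between days was not possible, since the full model leaves no residual degree of freedom.

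Before the data were examined, the design, the alternatives, the rule for named genes and 34 gene lists were fixed. Of 744 listed genes, 739 were in the tables and 627 passed the filter. The lists included osteoblast transcription factors, bone matrix and mineralization, other collagens and matrix, matrix proteases, YAP and TAZ targets, SRF and MRTF contractile targets, focal adhesion and integrins, nuclear lamina and LINC complex, histone acetyltransferases and deacetylases, histone methyltransferases and demethylases, and DNA methylation and chromatin remodelling. Further lists were S phase genes, G2 and M phase genes, TGF-beta targets, BMP targets, Wnt pathway targets and inhibitors, immediate early genes, inflammatory cytokines and NF-kB targets, interferon-stimulated genes, hypoxia and glycolysis, cholesterol synthesis, the integrated stress and unfolded protein responses, NRF2, metal and heat shock responses, and p53 targets. Cell type lists were adipocyte, chondrocyte, smooth muscle and pericyte, stromal stem cell, macrophage and leukocyte, osteoclast, endothelial, erythroid, and nerve and Schwann cell markers. Each list is given as its median log2 ratio with a 95% counting interval and as the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. Of the lists and of the genes taken by the naming rule, 1 list and some genes are not reported here. No percentile is given for lists with fewer than 3 measured genes.

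The rule for named genes took, in each comparison, the 5 highest and 5 lowest ratios among 2-fold genes with at least 100 reads in 1 library, leaving out symbols that are only locus identifiers and mitochondrial or ribosomal RNA genes. For both days together it took up to 10 genes on each side that were 2-fold apart in the same direction on both days. These needed at least 100 reads in 1 library of each day. Members of the lists could be named, first the 2 to 4 largest differences at 100 reads or more. Runx2, Sp7, Alpl, Col1a1, Spp1, Ibsp, Bglap, Ccn1, Ccn2, Ankrd1, Lmna and Yap1 were named whatever their values.

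The alternatives were other scalings (DESeq2 size factors, library totals, and totals without the 10 most abundant genes), no filter or a filter at 5 CPM, pseudocounts of 0.1 and 2 CPM, a 1.5-fold threshold, an interval excluding 1.5-fold, DESeq2 1.42.0 and limma-voom from limma 3.58.1. Thinning every library to the smallest total was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.

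Both procedures were tested on simulated data drawn for the 13086 genes. The 2-fold rule recovered 91% of 200 genes changed by 1.5 on the log2 scale at day 1 and 91.5% at day 3 when the dispersion of the additive fit was simulated, and it counted 32 and 3 unchanged genes. That dispersion was the same for every gene and was not measured between replicate cultures. The simulation therefore does not show how many unchanged genes the rule counts if cultures vary more. For the surface effect, the additive test recovered 85% of 100 genes changed 2-fold and 97% of 100 changed 4-fold, with 3 unchanged genes called. That simulation gave every gene the same dispersion, no day effect and a surface effect equal on both days. It therefore does not show how the test performs where the surface effect differs between days or the spread differs between genes.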

Results

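The series measured gene expression by RNA sequencing in rat bone marrow-derived mesenchymal stem cells, which can form bone, cartilage and fat cells, during the opening days of osteogenic culture. It asked whether a wave-forming nanotexture on titanium primes these cells for osteogenesis, with mechanotransduction and chromatin regulation named in its title. There were 4 libraries, 1 each for flat and wave discs at day 1 and day 3, with totals between 10575759 and 20320492 reads. Between 17436 and 18672 genes had at least 1 read. The 10 most abundant genes held 16.2% and 15.9% of reads on flat and wave at day 1, and 14.9% and 14.8% at day 3. Col1a1, the main chain of the collagen of bone, held 3.69%, 3.39%, 3.88% and 3.41% of reads in flat day 1, wave day 1, flat day 3 and wave day 3. Mitochondrial ribosomal RNA held 2.68% of reads on flat and 2.14% on wave at day 1 (exact 95% intervals 2.67 to 2.69 and 2.13 to 2.15), and 3.08% and 3.46% at day 3 (3.07 to 3.09 and 3.45 to 3.47).

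At day 1, the wave surface carried higher transcript levels of several mineralizing-matrix genes and lower levels of elastin and cholesterol synthesis genes than the flat surface. Spp1 (osteopontin) was 2.98-fold higher on wave (log2 ratio 1.58, 95% counting interval 1.55 to 1.61) and Ibsp (bone sialoprotein) 2.47-fold higher (1.30, 1.22 to 1.40). Bglap (osteocalcin) had 7 reads on wave and 0 on flat, at least 3.07-fold higher with 3 reads put on flat, while the counting interval of the log2 ratio began at 0.92. Eln, which encodes elastin, was 5.54-fold lower on wave (-2.47, -3.06 to -2.15). In all, 92 genes were at least 2-fold higher and 199 at least 2-fold lower among 13086.

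Among genes with at least 100 reads in a library, the largest ratios at day 1 were those of Cxcl13, a chemokine (2.45, 2.11 to 3.33), Itga10, an integrin subunit that binds collagen (2.23, 1.95 to 2.74), and Anxa8 (1.85, 1.52 to 2.46). They were followed by Igfbp3, a binding protein of insulin-like growth factors (1.85, 1.64 to 2.13), and by Kcnn4, a calcium-activated potassium channel (1.75, 1.55 to 2.02). Below Eln, the lowest of these genes were Gja5, a connexin (-1.95, -2.30 to -1.70), Tril (-1.78, -2.03 to -1.59), Egfl6 (-1.77, -2.78 to -1.31) and Ca3, a carbonic anhydrase (-1.72, -2.64 to -1.27).

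Among bone genes at day 1, the bone matrix and mineralization list had a median log2 ratio of 0.25 (0.02 to 0.30), at percentile 100 of matched random lists. Of its 19 measured members, 5 were at least 2-fold higher on wave (Phex, Spp1, Ibsp, Mgp and Bglap) and 0 were 2-fold lower, and in all 11 had a ratio above 0 and 8 below, with Bmp4 at least 1.5-fold lower (-0.68, -1.15 to -0.29). Phex rested on 2 and 20 reads (1.92, 1.68 to 6.86), while Mgp, an inhibitor of mineralization, rested on 428 and 788 (1.26, 1.10 to 1.45). Alpl, the alkaline phosphatase of mineralizing cells, differed less (0.25, 0.13 to 0.38), and Col1a1 was slightly lower (-0.12, -0.13 to -0.11). The 12 osteoblast transcription factors had a median near 0 (-0.04, -0.12 to 0.05, percentile 26.1), with Runx2 at -0.07 (-0.22 to 0.07) and Sp7 (osterix) at 0.37 (0.24 to 0.50). Chondrocyte markers had a median of 0.54 (0.16 to 0.85, percentile 99.97), but of the 8 measured members only Acan, Sox6 and Sox9 had 100 reads or more in a library. Acan, the core protein of aggrecan, was higher (1.03, 1.00 to 1.06), as was Sox6 (0.77, 0.47 to 1.12), while Sox9 was lower (-0.18, -0.36 to 0.00).

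Sterol genes were lower on wave at day 1. All 23 cholesterol synthesis genes had a ratio below 0, with a median of -0.64 (-0.67 to -0.56, percentile 0), and 13 were at least 1.5-fold lower. Insig1, a sensor of sterol levels, was at -0.89 (-1.0 to -0.79), Hmgcs1, an early enzyme of the pathway, at -0.86 (-0.93 to -0.80) and Nsdhl at -0.77 (-0.94 to -0.61). Proliferation genes were higher on wave. Of 30 S phase genes, 27 had a ratio above 0 (median 0.31, 0.26 to 0.35, percentile 100), led by Cdt1 (0.68, 0.48 to 0.91) and E2f1 (0.67, 0.49 to 0.87). The same held for 26 of 32 G2 and M phase genes (median 0.10, 0.07 to 0.14, percentile 99.7), with Kif11 at 0.30 (0.19 to 0.41). Stromal stem cell markers were lower (median -0.22, -0.28 to -0.14, percentile 0.07), including the receptor gene Pdgfrb (-0.90, -0.97 to -0.82) and Cxcl12 (-0.60, -0.68 to -0.53).

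Of the remaining signalling and matrix lists at day 1, 4 lay above the middle 95% of random lists. Immediate early genes had a median of 0.13 (0.02 to 0.17, percentile 99.8) with Klf4 at 0.93 (0.73 to 1.16). The other collagens and matrix genes had a median of 0.09 (0.05 to 0.11, percentile 99.4) with Tnc at 0.73 (0.70 to 0.76) and Postn at 0.64 (0.62 to 0.66). Medians were 0.11 for the NRF2, metal and heat shock genes (0.04 to 0.17, percentile 98.1) and, for TGF-beta targets, 0.11 (0.04 to 0.14, percentile 97.7) with Tgfbi at 0.97 (0.78 to 1.20). Inflammatory cytokines and NF-kB targets (median -0.20, -0.25 to 0.00, percentile 1.95) and p53 targets (median -0.13, -0.21 to -0.08, percentile 1.23), with Tp53inp1 at -0.89 (-1.15 to -0.66), lay below it. Together 8 lists lay above and 4 below. Lists of independently drawn genes would give 1.60 on both sides together, but the genes of a list can vary together between single cultures. The excess over that number is therefore no measure of a surface effect.

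The mechanotransduction lists given here had medians from 0.02 to 0.10 at day 1, although single members lay far apart. The median of 23 YAP and TAZ targets was 0.08 (-0.01 to 0.11, percentile 96.5), with Igfbp3 the only one at least 2-fold higher and none 2-fold lower. Values were 0.08 for Ccn1 (0.05 to 0.12), 0.31 for Ccn2 (0.29 to 0.33) and -0.03 for Yap1 itself (-0.10 to 0.05), and Ankrd1 had 5 and 11 reads (0.85, -0.11 to 3.41). Nuclear lamina and LINC complex genes, which couple the nucleus to the cytoskeleton, had a median of 0.10 (0.04 to 0.17, percentile 97.0), with Lmna (lamin A/C) higher (0.50, 0.47 to 0.54). SRF and MRTF contractile targets (median 0.02, percentile 67.1) and focal adhesion and integrin genes (0.04, percentile 87.1) had medians near 0. Within the integrins, Itga10 and Itga7 (1.35, 0.88 to 2.24) were at least 2-fold higher and Itga8 (-1.37, -1.92 to -1.0) at least 2-fold lower. Chromatin regulators were likewise close to 0, at -0.05 (percentile 10.5) for 27 histone acetyltransferases and deacetylases, -0.01 (percentile 25.2) for 42 histone methyltransferases and demethylases and 0.01 (percentile 55.9) for 35 DNA methylation and remodelling genes, where Hmga1 was at 0.52 (0.43 to 0.62).

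The other lists lay inside the middle 95% of random lists at day 1. Their medians were -0.07 for Wnt pathway genes (percentile 15, Sfrp1 -0.92, -1.12 to -0.74) and 0.00 for hypoxia and glycolysis (percentile 45.9). BMP targets had a median of 0.09 (percentile 89.8), with Nog at least 2-fold lower and Hey1, from 11 reads on flat and 0 on wave, at least 2.79-fold lower. Medians were -0.03 for the integrated stress and unfolded protein responses (percentile 20.6), -0.10 for interferon-stimulated genes (percentile 13.2) and 0.01 for matrix proteases (percentile 53.2). Among the proteases and inhibitors, the collagenase gene Mmp13 was at 2.62 (2.30 to 4.38) from 10 and 73 reads and Timp3 at 1.24 (0.88 to 1.76).

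**Figure D1:**
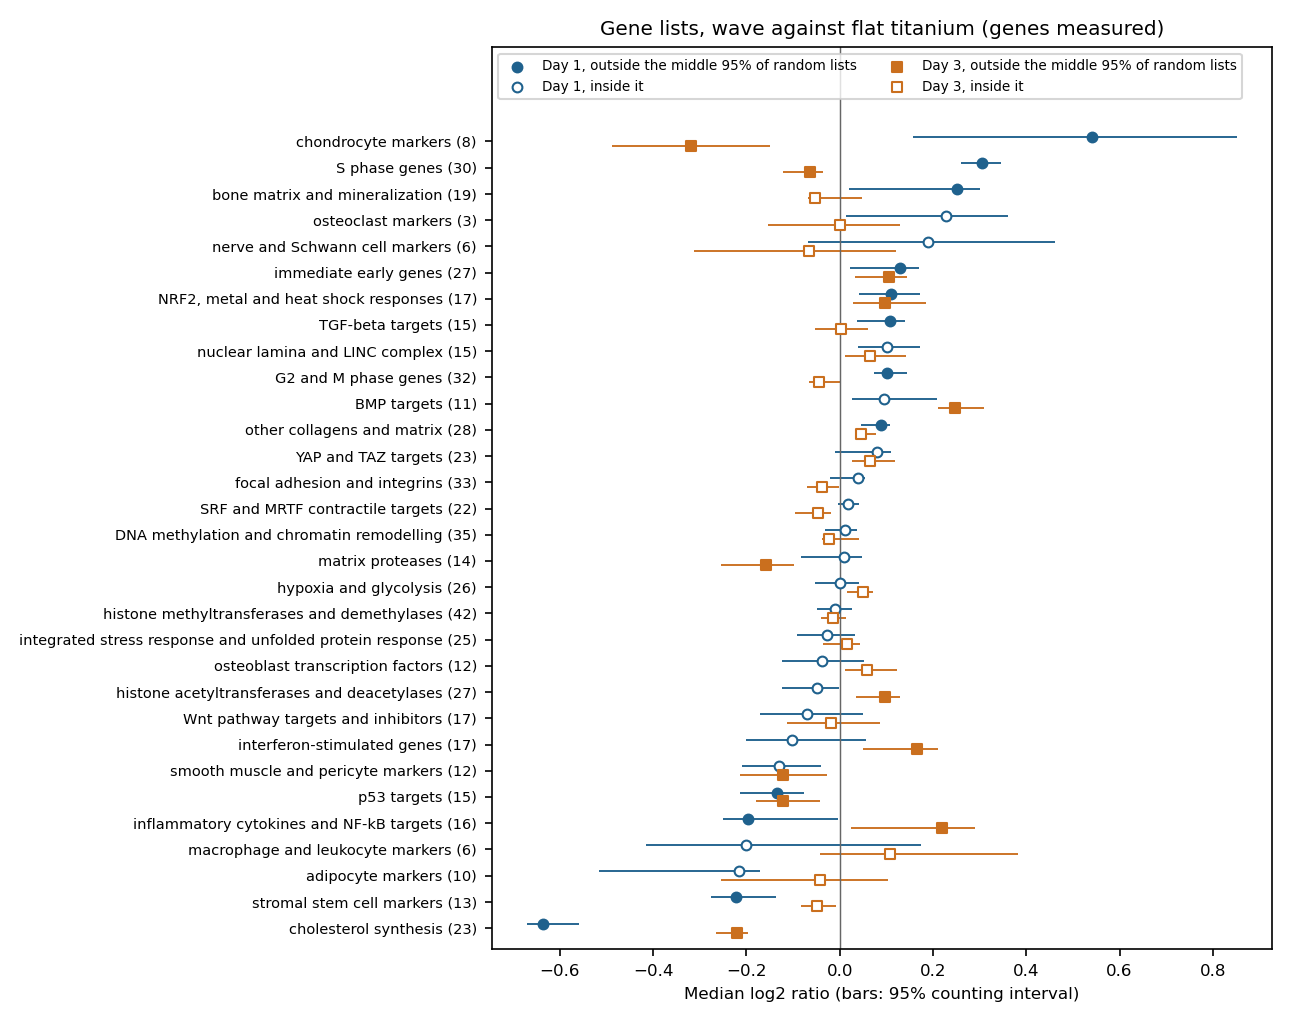
Median log2 ratio of each gene list reported, wave against flat, at day 1 (blue circles) and day 3 (orange squares), with bars for 95% counting intervals and filled symbols for medians outside the middle 95% of random lists of matched expression; the number of measured genes is in parentheses. Cholesterol synthesis genes lie lowest at day 1, at -0.64, and chondrocyte markers highest, at 0.54, on both sides of lists that mostly lie near 0.

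At day 3 the bone matrix difference was small, and the wave surface carried higher levels of Aldh3a1, Adh7, Nqo1 and BMP targets. Aldh3a1, an aldehyde dehydrogenase, was 4.11-fold higher on wave (2.04, 1.94 to 2.17), Adh7, an alcohol dehydrogenase, 3.49-fold higher (1.80, 1.58 to 2.29), and Nqo1, a quinone reductase and NRF2 target, was at 1.31 (1.26 to 1.37). Igf2, a growth factor, was 3.86-fold lower (-1.95, -2.43 to -1.73) and the integrin gene Itga8 4.02-fold lower (-2.01, -2.51 to -1.78). In all, 32 genes were at least 2-fold higher and 56 at least 2-fold lower. The day 1 libraries held fewer reads, so the counts of the 2 days are not at equal depth. With every library thinned to the smallest total, 292 genes were 2-fold apart at day 1 and 145 at day 3.

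Further named genes at day 3 were Dpp4, a cell surface peptidase (1.90, 1.68 to 2.38), Ppl (1.64, 1.38 to 2.30) and Myo7a, a myosin (1.63, 1.52 to 1.78), all higher on wave. Lower on wave were Ccn3 (-1.62, -2.25 to -1.35) and Npr3, a natriuretic peptide receptor (-1.53, -1.82 to -1.34). Asdurf had 175 reads on flat and 0 on wave, at least 56.9-fold lower, but it shares its locus with Asnsd1, which hardly differed (-0.02, -0.13 to 0.08), so its count is uncertain. It had 0 reads in both day 1 libraries.

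The bone matrix and mineralization list had a median of -0.05 at day 3 (-0.07 to 0.05, percentile 14.7). Spp1 (0.04, 0.02 to 0.06), Ibsp (-0.05, -0.08 to -0.03), Alpl (-0.06, -0.10 to -0.02) and Col1a1 (-0.18, -0.18 to -0.17) were nearly level between surfaces, Bglap was higher on wave (1.09, 0.87 to 1.42) and Mgp was lower (-0.998, -1.17 to -0.86). Osteoblast transcription factors had a median of 0.06 (0.01 to 0.12, percentile 88.3), with Runx2 at 0.09 (0.03 to 0.16), Sp7 at 0.06 (0.00 to 0.12) and Dlx3 at 0.45 (0.28 to 0.63). BMP targets were higher on wave (median 0.25, 0.21 to 0.31, percentile 99.96), and 9 of 11 had a ratio above 0. At least 1.5-fold higher were 5 of them, namely Id1 (0.77, 0.57 to 1.01), Smad9 (0.67, 0.48 to 0.89), Atoh8 (0.66, 0.51 to 0.82), Id2 (0.65, 0.50 to 0.83) and Id4, and Nog, a BMP inhibitor, was at least 1.5-fold lower (-0.60, -1.17 to -0.20).

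All 23 cholesterol synthesis genes again had a ratio below 0, by a smaller margin (median -0.22, -0.27 to -0.20, percentile 0), with Insig1 at -0.41 (-0.49 to -0.34). Inflammatory cytokines and NF-kB targets had a median of 0.22 (0.02 to 0.29, percentile 99.98), with 9 genes above 0 and 7 below. Ccl2 was at 1.20 (0.87 to 1.86), Ptgs2 at 0.70 (0.41 to 1.11) and Csf1 at 0.51 (0.48 to 0.54), while Tnfaip3 was at -0.38 (-0.71 to -0.10) and Il6 had 13 and 1 reads (-1.03, -9.07 to -0.93). Interferon-stimulated genes (median 0.17, 0.05 to 0.21, percentile 99.9) and immediate early genes (0.11, 0.03 to 0.14, percentile 99.9) were also above the middle 95% of random lists. So were histone acetyltransferases and deacetylases (0.10, 0.04 to 0.13, percentile 99.9) and the NRF2, metal and heat shock genes (0.10, 0.03 to 0.18, percentile 99.1). Below it were matrix proteases (-0.16, -0.25 to -0.10, percentile 0.12), with Adamts4 at -0.64 (-0.94 to -0.41), and p53 targets (-0.12, -0.18 to -0.04, percentile 0.58), with Plk2 at -0.84 (-1.04 to -0.68). S phase genes (-0.06, -0.12 to -0.03, percentile 2.28), chondrocyte markers (-0.32, -0.49 to -0.15, percentile 0.68) and smooth muscle and pericyte markers (-0.12, -0.21 to -0.03, percentile 0.91) also lay below it. Despite the chondrocyte median, Acan was higher on wave (0.50, 0.48 to 0.52).

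Mechanotransduction lists again had medians near 0 at day 3. The median was 0.06 for YAP and TAZ targets (percentile 97.1), with Tgfb2 at 0.60 (0.54 to 0.66), Ccn1 at 0.00, Ccn2 at 0.21 (0.19 to 0.24), Yap1 at 0.04 (-0.02 to 0.09) and Ankrd1 at 19 and 24 reads (0.25, -0.56 to 1.32). It was 0.06 for lamina genes (percentile 94.8), with Lmna at 0.23 (0.21 to 0.26) and Syne3 at 0.52 (0.43 to 0.60). Medians were -0.05 for SRF and MRTF contractile targets (percentile 7.30) and -0.04 for focal adhesion genes (percentile 8.84), where Itga3 was at 0.76 (0.70 to 0.83) and Lims2 at -0.80 (-1.15 to -0.55). Smooth muscle contractile genes stood out within the contractile list, with Cnn1 at -0.71 (-0.83 to -0.60), Actg2 at -0.63 (-0.71 to -0.56) and Acta2 at -0.61 (-0.64 to -0.59). The remaining medians were -0.01 for histone methyltransferases and demethylases, -0.02 for DNA methylation and remodelling genes, -0.02 for Wnt pathway genes and 0.00 for TGF-beta targets. They were 0.05 for hypoxia and glycolysis, 0.02 for the integrated stress and unfolded protein responses, -0.04 for G2 and M phase genes, -0.05 for stromal stem cell markers and 0.05 for other collagens and matrix, all inside the middle 95% of random lists.

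Macrophage, osteoclast, endothelial and erythroid markers were sparse. Macrophage and leukocyte markers passed the filter for 6 of 22 genes (median -0.20 at day 1, -0.42 to 0.18, and 0.11 at day 3, -0.04 to 0.38). Some of them were higher on wave, namely Lyz2 at day 1 from 32 and 57 reads (1.08, 0.58 to 1.90) and, at day 3, Mrc1 from 24 and 61 reads (1.08, 0.68 to 2.13) and Laptm5 (0.86, 0.57 to 1.31). Osteoclast markers passed for 3 of 10 (0.23, 0.01 to 0.36, and 0.00, -0.15 to 0.13) and nerve and Schwann cell markers for 6 of 10 (0.19, -0.07 to 0.46, and -0.07, -0.31 to 0.12). Endothelial markers passed for 2 of 13, among them Egfl7 (-0.29, -0.63 to 0.03, and -0.36, -0.69 to -0.07), and erythroid markers for 0 of 11. Adipocyte markers had medians of -0.22 at day 1 (-0.52 to -0.17, percentile 3.39), with all 10 below 0, and -0.04 at day 3 (-0.26 to 0.10, percentile 35.1), and Scd, a fatty acid desaturase on that list, was at -1.51 (-1.66 to -1.39) at day 1. Smooth muscle and pericyte markers had a day 1 median of -0.13 (-0.21 to -0.04, percentile 2.64), where Notch3 was at -1.52 (-1.77 to -1.33).

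**Figure D2:**
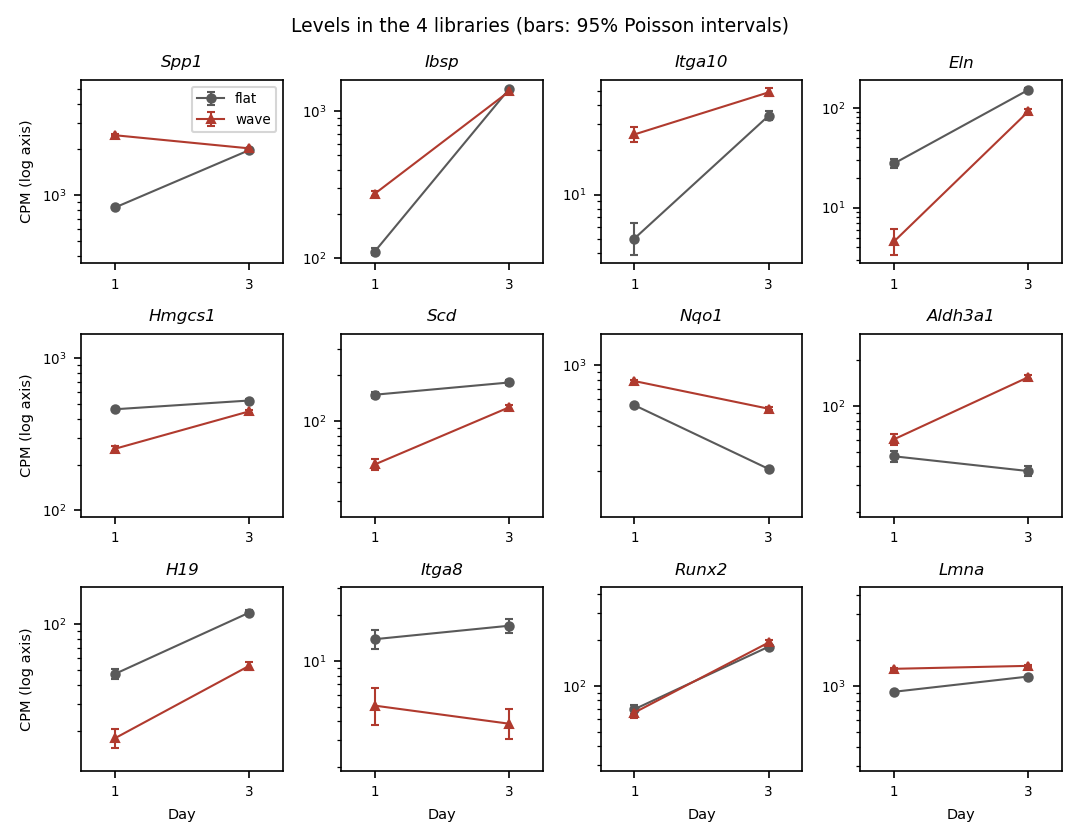
CPM (log axis) of 12 genes on flat (grey circles) and wave (red triangles) discs at day 1 and day 3, 1 library per point, with bars for 95% Poisson intervals. Spp1 and Ibsp differ between surfaces at day 1 and nearly coincide at day 3, whereas H19 and Itga8 lie lower on wave at both days.

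Surface differences at day 1 and at day 3 were weakly correlated across genes. Their log2 ratios had a Pearson correlation of 0.119 and a Spearman correlation of 0.0960 over 13086 genes, which are not independent replicates. Only Bglap, Dpp4 and Krt18, the last named after its values were seen, were at least 2-fold higher on wave on both days (3 genes, against 0.225 if the days were independent). At day 1 they rested on few reads, with 0 on flat and 7 on wave for Bglap, 4 and 17 for Dpp4 and 2 and 10 for Krt18. Of the genes higher on both days, 0 met the naming rule with its minimum of 100 reads. Numbers under independence take every gene as equally likely to be 2-fold apart. There were 14 genes at least 2-fold lower on both days, against 0.852. The 8 of these that met the naming rule were Itga8, Egfl6, Parm1 (-1.20 and -1.32), the imprinted noncoding RNA gene H19 (-1.38, -1.65 to -1.17, and -1.15, -1.27 to -1.06), Dhrs3, a retinal reductase (-1.35 and -1.14), Blnk (-1.54 and -1.13), Ccn3 and Kif26b (-1.51 and -1.03). The surface ratio of 400 genes differed at least 2-fold between the days, higher at day 3 for 217 and lower for 183, without a test of the difference. Spp1 (-1.54, -1.58 to -1.5) and Ibsp (-1.36, -1.46 to -1.27) were among genes whose surface ratio was lower at day 3.

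**Figure D3:**
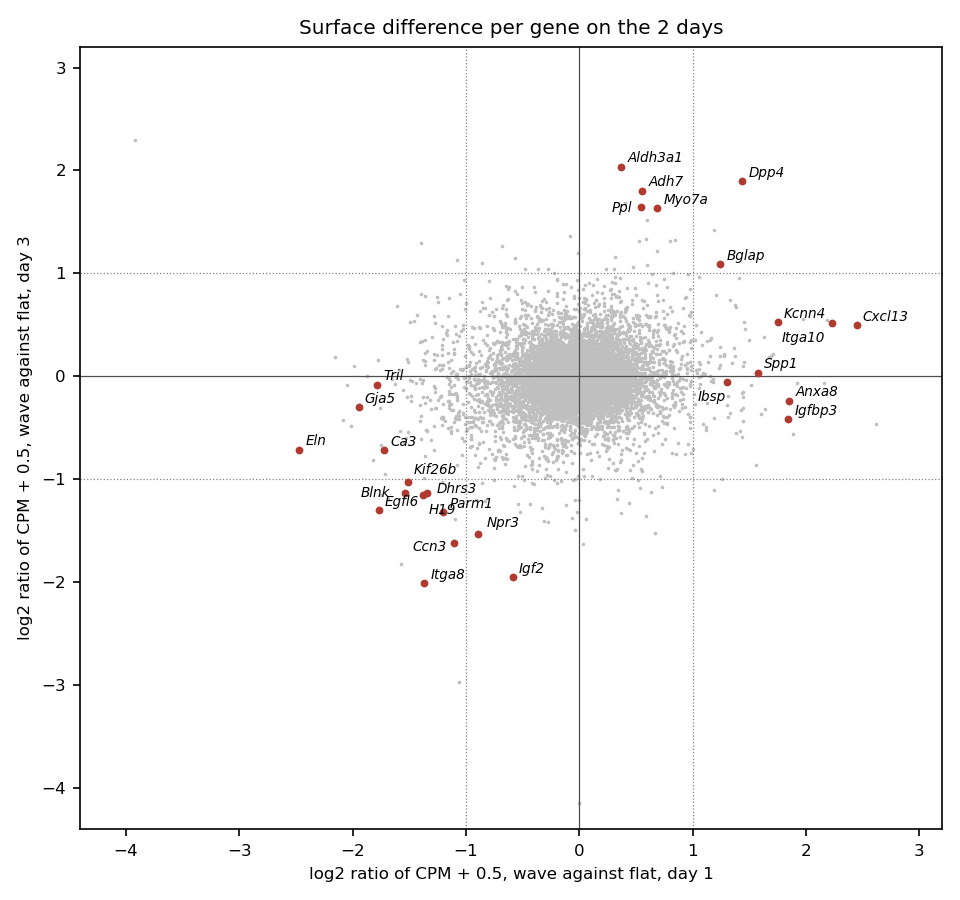
Log2 ratio of CPM plus 0.5, wave against flat, at day 1 (horizontal) and day 3 (vertical) for 13086 genes (grey), with named genes in red and dotted lines at 2-fold. The ratios of the 2 days have a Pearson correlation of 0.119, and Itga8, Egfl6 and H19 lie low on both.

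Averaged over both days, edgeR's quasi-likelihood test called 98 genes higher and 141 lower on wave (adjusted p under 0.05, 239 of 13086). The lowest adjusted p was that of H19 (log2 fold change -1.26, adjusted p = 1.57e-09), and Itga8 (-1.84, 3.83e-07), Nqo1 (0.92, 2.38e-06), Eln (-1.24, 2.32e-05) and Itga10 (1.16, 0.000342) were also called. The equal effect on both days that the model assumes was not met by Eln (-2.47 at day 1 and -0.71 at day 3) or Itga10 (2.23 and 0.52). The number of calls differed between tools and settings. DESeq2 called 30 genes (8 higher and 22 lower), edgeR with DESeq2 size factors 70 (26 and 44), limma-voom 273 (117 and 156) and edgeR without the filter 306 (129 and 177).

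By edgeR with TMM factors, cholesterol synthesis held the most surface calls of any list. By edgeR, 14 of its 23 genes fell on wave over all genes tested and 21 when adjusted over the list alone. Among them were Insig1 (-0.65, adjusted p = 4.02e-05), Hmgcs1 (-0.54, 0.00189) and Acat2 (-0.47, 0.00198). DESeq2 called 1 of them and edgeR with DESeq2 size factors 2, in both cases a number that at least 1 other list equalled. BMP targets had 4 genes that rose over all genes (Id1, Id2, Id4 and Grem1) and 6 that rose and 1 that fell when adjusted over the list alone. In the bone matrix list Spp1 (0.80, adjusted p = 0.00590), Ibsp (0.60, 0.0297) and Bglap (1.26, 0.00849) rose and Bmp4 fell, against 5 and 1 adjusted over the list alone, although Spp1 and Ibsp differed at day 1 far more than at day 3. The contractile genes Acta2 (-0.49, adjusted p = 0.00380), Actg2, Cnn1 (-0.45, 0.00924) and Myl9 fell, 4 of 22 by either adjustment. DESeq2 called none of the BMP and bone matrix genes and only Acta2 of the contractile genes, and edgeR with DESeq2 size factors called none of the genes of these 3 lists.

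Smaller surface counts by edgeR were given by other lists, first over all genes and then adjusted over the list alone. Lmna (0.37, adjusted p = 0.0379) and Syne3 rose among lamina genes (2, then 2), and Itga3 and Itga10 rose and Itga8 fell among integrin and focal adhesion genes (3, then 2 higher and 3 lower). Other collagens and matrix had Postn (0.47, adjusted p = 0.0128) and Loxl3 higher and Eln and Thbs2 lower (4, then 4 higher and 3 lower), and smooth muscle markers had Cspg4 higher and Myh11, Actg2 and Mylk lower (4, then 1 higher and 5 lower). Matrix proteases had Adamts4 and Plat lower (2, then 2 higher and 4 lower), and Wnt pathway genes Sfrp1 and Ccn5 lower (2, then 1 higher and 5 lower). Calls of 1 gene were Asap1 among YAP and TAZ targets (then 1), Hmga1 among DNA methylation and remodelling genes (then 1) and Klf4 among immediate early genes (then 2). They were also Ptgs2 among inflammatory genes (then 2), Nqo1 among NRF2, metal and heat shock genes (then 3) and Acan among chondrocyte markers (then 1). These were higher on wave, except 1 of the inflammatory genes called over the list alone. Tp53inp1 among p53 targets (then 2), Scd among adipocyte markers (then 2) and Pdgfrb among stromal markers (then 4, 1 of them higher) were lower. Hypoxia and stress response lists had 0 calls over all genes and 1 each over the list alone. Of the genes named in these lists DESeq2 called only Itga8, Myh11 and Acan, and edgeR with DESeq2 size factors only these and Plat, Sfrp1, Ccn5, Nqo1 and Scd. Klf4 was not called by limma-voom, nor Thbs2 by edgeR with the filter at 5 CPM.

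In 12 lists with 220 measured genes, edgeR made 0 surface calls by either adjustment, with 21 genes at an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0. Over all genes, 1081 of 13086 had an unadjusted p under 0.05 by edgeR. Among these lists were the osteoblast transcription factors, histone acetyltransferases and deacetylases, histone methyltransferases and demethylases, S phase, G2 and M phase, TGF-beta and interferon lists and the macrophage, osteoclast, endothelial and nerve marker lists. S phase genes had medians of opposite sign on the 2 days (0.31 and -0.06). The additive fit averages such differences and counts the departure as spread, so 0 calls there do not show equal levels on either day. Runx2 had a fitted log2 difference of 0.02 (edgeR adjusted p = 0.996), and Yap1 of 0.01 (0.999).

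From day 1 to day 3 on the flat surface, genes of late osteoblast and osteocyte matrix were higher and cell cycle genes lower. Ibsp was 12.7-fold higher at day 3 (3.67, 3.60 to 3.75), Dmp1, a marker of osteocytes, 18.5-fold higher (4.21, 3.98 to 4.72), and Bglap at least 34.7-fold higher. Alpl was 6.17-fold higher (2.63, 2.54 to 2.72), while Col1a1 was level (-0.01, -0.02 to -0.01). In all, 555 genes were at least 2-fold higher at day 3 and 428 at least 2-fold lower. At 100 reads or more in a library, the highest were Padi2, a peptidylarginine deiminase (5.59, 5.37 to 6.71), Rassf2 (4.73, 4.51 to 5.24), Capn6 (0 and 259 reads, at least 55.4-fold higher), Megf10 (4.37, 4.21 to 6.28) and Smpd3, a sphingomyelinase needed for mineralization (4.23, 4.01 to 4.71). The lowest at that depth were the keratin gene Krt7 (-3.20, -3.87 to -3.02), Fbln2 (-3.09, -3.29 to -2.97), Lrrc32 (-2.76, -3.24 to -2.56), Trib1 (-2.70, -3.88 to -2.52) and Col15a1 (-2.51, -2.67 to -2.40).

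On the wave surface the time course was similar. Dmp1 was 27.2-fold higher at day 3 (4.76, 4.48 to 5.43), Ibsp 4.97-fold higher (2.31, 2.26 to 2.37) and Bglap 14.8-fold higher (3.89, 3.58 to 5.96), while Spp1 was lower at day 3 (-0.29, -0.31 to -0.27), unlike on flat (1.25, 1.22 to 1.29). There were 649 genes at least 2-fold higher and 512 at least 2-fold lower. Besides Dmp1, Padi2 (4.58, 4.32 to 5.15), Smpd3 (4.40, 4.10 to 5.11), Sned1 (4.34, 4.06 to 4.93) and Rassf2 (4.20, 3.98 to 4.59) were highest at 100 reads or more. Among the lowest at that depth were the cadherin gene Cdh3 (-3.59, -4.89 to -3.47), Fbln2 (-2.86, -3.08 to -2.72), Krt7 (-2.56, -3.25 to -2.32) and Kcng1 (-2.37, -3.20 to -2.11). Time ratios on the 2 surfaces had a Pearson correlation of 0.761 across genes and a Spearman correlation of 0.722. They shared 319 genes at least 2-fold higher, against 27.5 if the surfaces were independent, and 252 at least 2-fold lower, against 16.8.

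Bone and cartilage genes were higher at day 3. The bone matrix and mineralization list had medians of 1.34 on flat (1.17 to 1.51) and 1.24 on wave (0.94 to 1.40). Osteoblast transcription factors had medians of 0.56 (0.47 to 0.64) and 0.69 (0.59 to 0.90), all at percentile 100, with Runx2 at 1.36 and 1.52 and Sp7 at 1.51 and 1.20. Chondrocyte markers had medians of 1.38 on flat (1.17 to 1.504, percentile 100) and 0.58 on wave (0.35 to 0.90, percentile 97.7), and all 8 were above 0 on both surfaces. Medians were 0.65 and 0.70 for 6 nerve and Schwann cell markers (percentiles 99 and 98.7) and 0.59 and 0.45 for 3 osteoclast markers (percentiles 98.2 and 95.5). All 30 S phase genes (medians -0.59 and -0.97) and all 32 G2 and M phase genes (-0.98 and -1.13) were lower at day 3 on both surfaces, at percentile 0. Rrm2, a ribonucleotide reductase subunit, was at -1.72 (-1.82 to -1.63) and -2.0 (-2.11 to -1.91). Contractile and adhesion genes were lower as well, with medians on flat and wave of -0.34 and -0.51 for SRF and MRTF targets and -0.27 and -0.34 for focal adhesion genes. YAP and TAZ targets had medians of -0.37 and -0.14 (percentiles 0.04 and 18.3), where Ccn2 was at -1.38 (-1.41 to -1.36) and -1.48 (-1.51 to -1.46). Interferon-stimulated genes were higher (0.47 and 0.71), and the NRF2, metal and heat shock genes lower (-0.56 and -0.41). Cholesterol synthesis genes had a median of 0.02 on flat (-0.03 to 0.07, percentile 83.0) and 0.42 on wave (0.32 to 0.45, percentile 100).

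Averaged over both surfaces, edgeR's quasi-likelihood test called 2352 genes higher and 2518 lower at day 3 (4870 of 13086), and DESeq2 called 1965. Of 19 bone matrix genes 11 rose and 1 fell over all genes (11 and 2 adjusted over the list alone), and 9 of 12 osteoblast transcription factors rose by either adjustment, including Runx2, Sp7 and Dlx5. Of 8 chondrocyte markers 5 rose, Sox9, Sox6 and Acan among them (6 adjusted over the list alone). In the cell cycle lists, 28 of 30 S phase and 32 of 32 G2 and M phase genes fell by either adjustment. Of 22 contractile targets 16 fell (16, with 1 that rose, adjusted over the list alone), of 17 NRF2, metal and heat shock genes 14 fell and 1 rose by either adjustment, and of 17 interferon-stimulated genes 11 rose and 0 fell by either adjustment. Among chromatin genes, 7 of 27 histone acetyltransferases and deacetylases rose, Hdac4, Hdac5 and Hdac9 among them, and 2 fell by either adjustment. Together these calls made up a smaller share of that list than the 4870 of 13086 called over all genes. Of 42 histone methyltransferases and demethylases 12 rose, among them Ezh1, and 8 fell, among them Ezh2 (13 and 8 adjusted over the list alone). Of 35 DNA methylation and remodelling genes 4 rose, including Tet1 and Tet2, and 13 fell by either adjustment, including Dnmt1, Uhrf1 and Hmga1.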

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

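The tests of explanations in this part were chosen only after the result was seen, and none of the differences between days given here was itself tested, because 1 library per group leaves no spread to test against. Gene lists whose median lay on opposite sides of 0 on the 2 days, and outside the middle 95% of random lists on both, were S phase genes, inflammatory genes and chondrocyte markers. The surface median at day 3 minus that at day 1 was -0.37 for S phase genes, 0.42 for inflammatory cytokines and NF-kB targets and -0.86 for chondrocyte markers. The chondrocyte value rests mostly on genes with few reads.

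Genes at least 2-fold apart in opposite directions on the 2 days were Bmx, Klf7, Spon1 and Ugt1a8, in an untested comparison. The log2 surface ratio at day 3 minus that at day 1 was 2.20 for Bmx (13, 2, 7 and 27 reads in flat day 1, wave day 1, flat day 3 and wave day 3), 6.21 for Klf7 (95, 0, 0 and 40 reads), -2.29 for Spon1 (2, 10, 56 and 20 reads) and 2.70 for Ugt1a8 (11, 0, 25 and 75 reads). The values of all these genes depend on the pseudocount, those of Klf7 and Ugt1a8 most, since each had 0 reads in at least 1 library. On the floor of 3 reads, Klf7 was at least 24.1-fold lower on wave at day 1 and at least 13.7-fold higher at day 3, and Ugt1a8 was at least 2.79-fold lower at day 1. How reads were assigned to genes is not given in the sources used here, so the counts of Klf7, with 0 reads in a library of each day, are uncertain.

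S phase genes had higher levels on wave at day 1 and were lower at day 3 than at day 1 on both surfaces. A wave culture behind the flat one in the course over time is a candidate explanation that these values do not decide. Genes at least 2-fold higher over time on flat had a median day 1 surface ratio of 0.233, against that explanation, but genes higher over time on wave had one of -0.297, which goes with it. Each set shares a day 1 library with the surface ratio, which pulls the medians apart in opposite directions. A difference in cell density or in timing of a cell cycle wave between the discs was not tested. With 1 library per group, a difference between these single cultures and an effect of the surface remain open.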

How the results depend on the processing

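Thinning was chosen after the data were seen, and the other alternatives were planned. The additive model sets flat against wave within each day, so no other paired analysis was run, and with 1 library per group no replicate could be left out. Of the counts and the correlation under alternatives, 40 stayed within the bounds set for them and 22 moved. A reversal was possible only for the correlation, which kept its sign. Genes 2-fold apart between surfaces numbered 110 at day 1 and 39 at day 3 with the filter at 5 CPM, which also gave 614 over time on flat, 148 with a surface ratio differing between days and a correlation between days of 0.167, from fewer genes by construction. A pseudocount of 2 CPM, which by construction shrinks ratios of low genes, gave 66 at day 1, 29 at day 3, 515 and 662 over time on flat and wave, 95 differing between days and a correlation of 0.152. A pseudocount of 0.1 CPM, which by construction shrinks ratios of low genes less, gave 199 at day 3. It also gave a correlation of 0.0909, the cause of which was not tested. The 1.5-fold threshold, looser by construction, gave 812, 481, 2656 and 2839 for day 1, day 3, time on flat and time on wave, and an interval excluding 1.5-fold gave 165 at day 1. Thinning, which by construction leaves fewer reads and more counting noise at day 3, gave 145 at day 3, where 67 were shared with the 88 at full depth. DESeq2 called 1965 genes for day and 30 for surface, and edgeR with DESeq2 size factors called 70 for surface, where the prior degrees of freedom were 11.5 instead of 32.2; the cause was not tested. Among list medians 711 stayed and 57 moved, 35 of them under library totals, and among named-gene values 3639 stayed and 113 moved. Library totals also changed the balance of genes 2-fold apart over time. On flat they gave 656 higher and 353 lower, against 555 and 428, and on wave 753 and 435, against 649 and 512. Putting genes with 0 reads at their bound moved 1 of 9 affected list medians by more than 0.01, nerve and Schwann cell markers over time on flat, from 0.65 to 0.72. Depth limits genes near the filter: 12370 genes had 10 reads or more on wave at day 1 against 13622 on flat at day 3.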

Other observations

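The lists and genes in this part were chosen after their values were seen, as were all tests given here. Beside cholesterol synthesis, genes of fatty acid synthesis and desaturation were lower on wave. All 9 measured members had a ratio below 0 at both days, with medians of -0.54 at day 1 (-0.65 to -0.46) and -0.28 at day 3 (-0.33 to -0.24), both at percentile 0. The desaturase genes Scd2 (-1.28, -1.32 to -1.24) and Fads2 (-0.94, -1.05 to -0.83) followed Scd at day 1. Elastic fibre genes were also lower at day 1 (median -0.37, -0.52 to -0.25, percentile 0) and less so at day 3 (-0.08, -0.26 to 0.00, percentile 7.92). That list includes Eln itself, already known to be low, and 2 of its 12 members were above 0 at day 1 and 5 at day 3. Besides Eln, Fbln5, which binds elastin, was at -1.72 (-1.88 to -1.58) and Fbn2, a fibrillin gene, at -1.31 (-1.48 to -1.16) at day 1.

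Other single genes stood out. Igf1 was lower on wave at day 3 (-1.21, -1.52 to -0.99), as was Igf2, and the keratin gene Krt8 was higher (0.89, 0.65 to 1.22). Rn7sl1, a signal recognition particle RNA, had 849, 1467, 689 and 645 reads in flat day 1, wave day 1, flat day 3 and wave day 3. Asdurf, Klf7 and Moap1 were the 3 genes with at least 30 reads on a surface and 0 on the other at the same day. Moap1 had 32, 9, 72 and 0 reads in the same order and was at least 23.4-fold lower on wave at day 3. The assignment of reads to genes is not given in the sources used here, so the counts of these 3 genes are uncertain and their values need not be surface differences.

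Lower cholesterol synthesis on wave at day 1 could in principle come from the smaller wave library or from fewer adipocyte-like cells. With every library thinned to the smallest total the median was -0.64. Thinning nearly keeps the expected ratio of each gene, so it could hardly have moved this median and cannot decide about depth. The median was -0.62 under DESeq2 size factors and -0.64 under library totals, scalings that moved the median of all genes by at most 0.0141. Adipocyte markers that are not lipid synthesis enzymes had a median of -0.18 (-0.44 to 0.02) from 6 measured genes, some with few reads, so a part played by such cells at day 1 stays open. At day 3 their median was 0.11 (-0.04 to 0.28), with 5 of 6 above 0, while cholesterol synthesis was still lower. A lower activity of the sterol-sensing regulators of these enzymes is a hypothesis that was not tested.

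The higher Nqo1, Aldh3a1 and Adh7 on wave at day 3 may reflect a shared response to electrophiles or aryl hydrocarbon receptor ligands. Cells of another type stay open. The summed level of 10 macrophage and epithelial transcripts gained 0.523 CPM (counting standard error 0.728) while Nqo1 gained 309 CPM. The 5 of them with 0 reads in every library were the epithelial ones (Epcam, Cdh1, Krt19, Krt14 and Krt5), which gives no sign of cells expressing these genes. Yet macrophage and epithelial genes outside that sum were higher on wave, namely Krt8, Krt18 (1.42, 1.16 to 3.60), Slc11a1 (1.37, 1.09 to 1.92), Mrc1 and Laptm5. Others were not, as Krt7 had 55 and 52 reads (-0.04, -0.62 to 0.53), and of the 6 measured macrophage and leukocyte markers 4 were above 0 and 2 below. The 6 NRF2 targets other than Nqo1 had a median of 0.26 (0.20 to 0.37), at percentile 100 of random lists, and at day 1 of 0.13 (percentile 94.5). Of the aryl hydrocarbon receptor targets, Cyp1b1 (0.82), Ahrr (0.79) and Tiparp (0.88) were higher, Ugt1a6 was level (0.01) and Cyp1a1 had 1 and 3 reads (0.24, -2.02 to 7.34). The median of these 5 was 0.79 (0.71 to 0.84), at percentile 100. The 7 genes that include Nqo1 and Aldh3a1 had medians of 0.22 at day 1 and 0.82 at day 3. From day 1 to day 3 the median of these 7 was -0.91 on flat, with 1 gene above 0, and -0.22 on wave, with 3 above 0. Nqo1 was lower at day 3 on both surfaces (-1.39 on flat and -0.60 on wave), while Aldh3a1 was higher on wave (1.35). The NRF2 targets and the 5 receptor targets share no gene and both had medians above 0, so neither response is excluded, and a difference between single cultures remains open.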
